A study of Mus musculus with 14 samples.

How the data were processed

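The series profiled poly(A) sites, the positions where mRNAs end, in 3T3 cells, a mouse fibroblast line. It lists 14 samples. The 12 analysed here were made by 2P-Seq, in which poly(A)-selected RNA was partly digested with RNase T1, reverse transcribed from the poly(A) tail, circularised, amplified and sequenced from the tail, per the labels' protocols. They were 2 control libraries, 1 library each after 1, 2, 4 and 8 h of actinomycin D at 10 µg/ml, and 6 libraries from the fractions of a sucrose gradient. The 2 libraries made by 3P-Seq, a ligation-based 3' end assay, in 3T3 and mouse embryonic stem cells, were not analysed here, so distal 3' end use and gene level in stem cells against 3T3 cells, and the agreement of 3P-Seq with 2P-Seq, were not compared.

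The authors' deposited table holds raw counts of reads at 33590 poly(A) sites, which they annotated from 3P-Seq in both cell types, with positions in the mm9 build, per the file headers. The aligner was Bowtie, per the submitters' processing notes, and its version is not given in the sources used here. The file headers give 1 factor per library by which the authors divided the counts. The column names carry the control number or the hours. The fraction columns are named 0, 1, 2.5, 4.5, 7.5 and 12, and were taken as fractions 1 to 6 in ascending order, an assumption under which fraction 6 is the heaviest. Per-sample columns left unused numbered 0. The authors' filter was tested on the values: 17970 sites pass it, and 0 of the failing sites have 10 or more reads in control 1, the smallest count among passing sites being 10. The authors' deposited table also gives a half-life and the ribosomes per mRNA of each site. Recomputed from the counts and the factors, ribosomes per mRNA was the mean of the numbers in the fraction names, weighted by the scaled counts, for 30164 of 30164 sites within 1e-06. The unit and the fit of the half-life are not stated in the file headers. For 2000 of 2000 randomly drawn sites with at least 20 counts in each library, the rate behind it equalled that of an exponential least-squares fit on hours plus 0.1 per h, within 0.001 per h. The half-life was therefore read in hours, a site with no fall after scaling has 6.93 h, and values stop at 50 h, which 209 sites hold.

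The file does not pair sites with gene names, and no annotation of mm9 was used here. Positions were not converted between builds. The tests planned per gene were therefore run per locus: 3' ends on the same chromosome and strand, each within 2000 nt of the next, formed 1 locus. This gave 17807 loci, 10141 with a single 3' end and 7666 with 2 or more, the longest spanning 6245 nt. A locus can join neighbouring genes on a strand. The gene lists fixed beforehand could not be used without names.

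Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, TMM scaling and Benjamini-Hochberg adjustment over the loci or pairs tested, called at an adjusted p under 0.05. Loci needed 60 counts over the 6 libraries of a fit. For actinomycin D the model was a slope on hours, with the controls at 0 h. For the gradient it was a slope on fraction number. A slope is a log2 change per hour or per fraction relative to the rest of the library. For 3' end isoforms, the 2 most abundant ends of a locus with at least 60 counts each formed a pair, the end closer to the 5' side being proximal. The pair model had a term per library, an isoform term and the isoform by hours (or fraction) interaction, so each comparison was made within libraries. The median over pairs of log2((distal + 0.5)/(proximal + 0.5)) was correlated with hours or fraction number by Pearson's r and Spearman's rho, with two-sided exact permutation over all 720 pairings. Nothing says that the controls came from separate cultures, and each time and fraction has 1 library, so p-values measure only the spread of these libraries around a straight line, which may be technical. The gradient was run once. Shares carry Wilson 95% intervals and ratios of counts exact 95% intervals. For reads these cover counting error only, since PCR reads are not independent molecules. For shares of loci or pairs they take these as independent, though all share the same 6 libraries. CPM and ratios of counts use library totals, while slopes of loci use TMM scaling.

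Library totals ran from 1663346 counts (fraction 1) to 11575417 (fraction 6). In data simulated from the real means, 52.2% of loci with a slope of 0.2 per hour and 92.4% with 0.4 were recovered after actinomycin D (10734 loci), and 25.4% and 69.7% of pairs (3844 pairs). Over the gradient, 3% of loci with a slope of 0.4 and 63.6% with 0.8 per fraction were recovered (11135 loci), and 73.1% and 93.9% of pairs (4283 pairs). Each slope was given to only 66 or 67 loci or pairs. After actinomycin D, 105 simulated loci were called against 5945 real ones, so the adjusted threshold was stricter in the simulation. The shares for those loci may therefore understate recovery in the real data. For gradient pairs the reverse holds: 132 simulated pairs were called against 15 real ones. The adjusted threshold was looser in that simulation, and its shares may overstate recovery in the real data.

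Named loci and pairs were those with the largest slopes past the threshold, with at least 300 counts and the same direction in every fit that left out 1 library, at most 2 per direction because no names could be given. The tests, the rule for named items and the alternatives of scaling (RLE), tool (DESeq2 1.42.0), count minimum, choice of ends, added count, rank of the time and leaving out each library were fixed before the data were examined. Other linkage distances, single 3' ends, the header's factors, the authors' filter, a minimum distance of 100 nt, libraries thinned to 1 total and the numbers in the fraction names as covariate were chosen after seeing the data. Summaries used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.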

Results

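Where an mRNA ends sets how much 3' untranslated sequence it carries. The study measured, in mouse 3T3 fibroblasts, how the choice between neighbouring 3' ends goes with mRNA stability and with the number of ribosomes on the mRNA. Read counts at 33590 poly(A) sites were available from 2 control libraries, from cells treated with actinomycin D, which blocks transcription so that existing mRNAs decay, for 1, 2, 4 or 8 h, and from 6 fractions of a sucrose gradient, in which mRNAs with more ribosomes sediment further. The controls held 5843403 and 6433503 counts, the 1, 2, 4 and 8 h libraries 6111232, 5858649, 5048797 and 4045420, and fractions 1 to 6 held 1663346, 4173629, 6668635, 9200657, 10420511 and 11575417. Across sites, the controls correlated with a Pearson r of 0.978 and a Spearman rho of 0.951 on log2(CPM + 1). Sites are not independent replicates. Their log2 ratio had an SD of 0.42 over 8285 sites with at least 200 control reads, and the chi-square per degree of freedom was 19.2, so they differed by more than counting error with reads taken as independent molecules, which PCR reads are not. The 10 most abundant sites took 7.46% and 6.61% of the counts in the controls and 13% after 8 h of actinomycin D. They took 21.9% in fraction 1 and 7% in fraction 6.

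After actinomycin D, mRNA loci spread apart. Of 10734 loci tested, 3402 fell relative to the library, with a median slope of -0.33 log2 per hour, and 2543 rose, with a median of 0.18 log2 per hour (edgeR quasi-likelihood test, adjusted p under 0.05). Rises and falls are relative to the rest of the library. The fastest falls named by the rule were nearly complete within 1 h. A locus on chromosome 13 (plus strand, ends at 42403287 and 42403357, mm9) held 27 and 21.5 CPM in the controls. It held 1.31 CPM at 1 h, 0.512 CPM at 2 h and 0 counts at 4 and 8 h (slope -2.93 ± 0.28 SE, edgeR adjusted p = 7.07e-05). Its ratio of CPM at 8 h to the controls had an exact upper limit of 0.0381. A locus on chromosome 16 (plus strand, 30602812 to 30602876) went from 25.7 and 21.5 CPM to 1.96 CPM at 1 h. It had 0 counts at 8 h (slope -2.62 ± 0.30, edgeR adjusted p = 1.32e-04), and the exact upper limit of its ratio was 0.0391. Both limits are by library totals and would be higher with the TMM scaling of the slopes. Fitted slopes of loci that reach 0 counts are no bound on the rate and depend on the tool: DESeq2 gave slopes of -1.17 and -1.27 for these loci.

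Among the rising loci, a single 3' end on chromosome 15 (minus strand, 98357614) went from 11.3 and 4.51 CPM in the controls to 2.62 CPM at 1 h, 14 at 2 h, 34.7 at 4 h and 143 at 8 h, 18.4-fold above the controls (exact 95% interval 14.8 to 23.1, slope 0.69 ± 0.09, edgeR adjusted p = 6.42e-04). A more abundant end on the same chromosome (minus strand, 36538656) went from 640 and 276 CPM to 197 CPM at 1 h and 4646 CPM at 8 h, 10.3-fold above the controls (exact interval 10.0 to 10.6, slope 0.60 ± 0.11, edgeR adjusted p = 0.0063). At both ends the controls differed more than 2-fold from each other, and the 1 h library lay below both. Both ends also rose with the header's factors, with slopes of 0.53 and 0.44. The folds and their intervals are by library totals, while the slopes of 0.69 and 0.60 use TMM. The TMM factors were 0.66 at 8 h and 1.22 and 1.29 in the controls, so the folds are larger on that scale.

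The split between rising and falling loci depends on the scaling. TMM and RLE hold the typical locus near 0, with median slopes of -0.035 and -0.022 log2 per hour, and RLE called 2800 rising and 3200 falling. The authors' factors moved the median slope to -0.20 and called 259 rising and 6441 falling, 3.9% rising against 42.8% with TMM. In the authors' deposited table, sites passing the filter had a median half-life of 2.88 h, with the middle 50% between 1.59 and 5.02 h.

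The central question of the study was whether 3' end isoforms of a gene differ in stability. In 3844 loci with a pair of 3' ends, 127 pairs had a distal end that was lost faster than the proximal end after actinomycin D and 40 had a distal end that was lost more slowly (edgeR, adjusted p under 0.05). The other 95.7% of pairs were not called. Over all pairs, the median difference of slopes was -0.019 log2 per hour, with the middle 50% between -0.12 and 0.06. For 528 pairs (13.7%), the 95% interval of the difference lay wholly within a 2-fold change over 8 h, and for 236 it lay wholly beyond one. These intervals are per pair and not adjusted over the pairs tested, so 236 is not a count of called differences. The median interval reached 0.16 log2 per hour to either side, so for most pairs a 2-fold difference was not detectable with these libraries. Over 1779 pairs with at least 300 counts per end, the log2 distal/proximal ratio differed between the controls by a median of 0.24 in size (SD of the difference 0.46), and between 8 h and the mean of the controls by 0.48 (SD 1.06). At 8 h it was lower than in the controls for 58.6% of those pairs. It was lower in control 1 than in control 2 for 57.6%.

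The number of called pairs rested on single libraries. Without control 1, 71 pairs with a faster and 10 with a slower distal end were called, without control 2 10 and 3, without the 1 h library 35 and 6, and without the 4 h library 15 and 3. Without the 8 h library, edgeR called 0 in each direction, with 412 and 166 at an unadjusted p under 0.05. Pairs under that unadjusted p moved less than the calls. They numbered 612 and 291 with all 6 libraries, 480 and 256 without control 2, and 573 and 288 without the 4 h library. On all 6 libraries, DESeq2 called 262 and 71.

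By 8 h, each named pair held reads at only 1 of its ends. On chromosome 2 (plus strand, proximal 166619887, distal 166621661), the distal end took 78.3% and 86.2% of the pair's reads in the controls, 45.6% at 1 h and 0 of 33, 43 and 10 reads at 2, 4 and 8 h, the last allowing up to 27.8% (slope difference -3.10 ± 0.35, edgeR adjusted p = 0.0175). On chromosome 12 (minus strand, 76732023 and 76731582), the distal share was 19.6% and 45.8% in the controls, which therefore disagreed, 18.8% at 1 h, 1.02% at 2 h and 0 of 1562 reads at 8 h (-1.65 ± 0.23, edgeR adjusted p = 0.0205). Its proximal end rose from 292 and 116 reads in the controls to 1562 at 8 h. The share of this pair therefore mixes loss of the distal end with a rise of the proximal end. In the other direction, the distal end on chromosome 8 (plus strand, 114543098 and 114544343) rose from 32.8% and 31.9% of the pair to 97.7% at 4 h and 31 of 31 reads at 8 h (1.26 ± 0.14, edgeR adjusted p = 0.01). The distal end on chromosome 1 (minus strand, 138165737 and 138164848) rose from 41.7% and 45.8% to 88.1% at 2 h and 6 of 6 reads at 8 h (1.04 ± 0.19, edgeR adjusted p = 0.0306). Each of these calls was lost without some library. Without the 8 h library the adjusted p was 0.0607, 0.128, 0.0877 and 0.128 in the order given, and without control 2 it was 0.0658, 0.0658, 0.0506 and 0.0785. Without the 4 h library it was 0.0649 and 0.0571 for the pairs on chromosomes 2 and 12 and 0.0756 for the pair on chromosome 1, which also lost its call without control 1 (0.0784) and without the 1 h library (0.0575). For the pair on chromosome 2, DESeq2 gave a slope difference of -1.19 with an adjusted p of 0.0804.

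**Figure D1:**
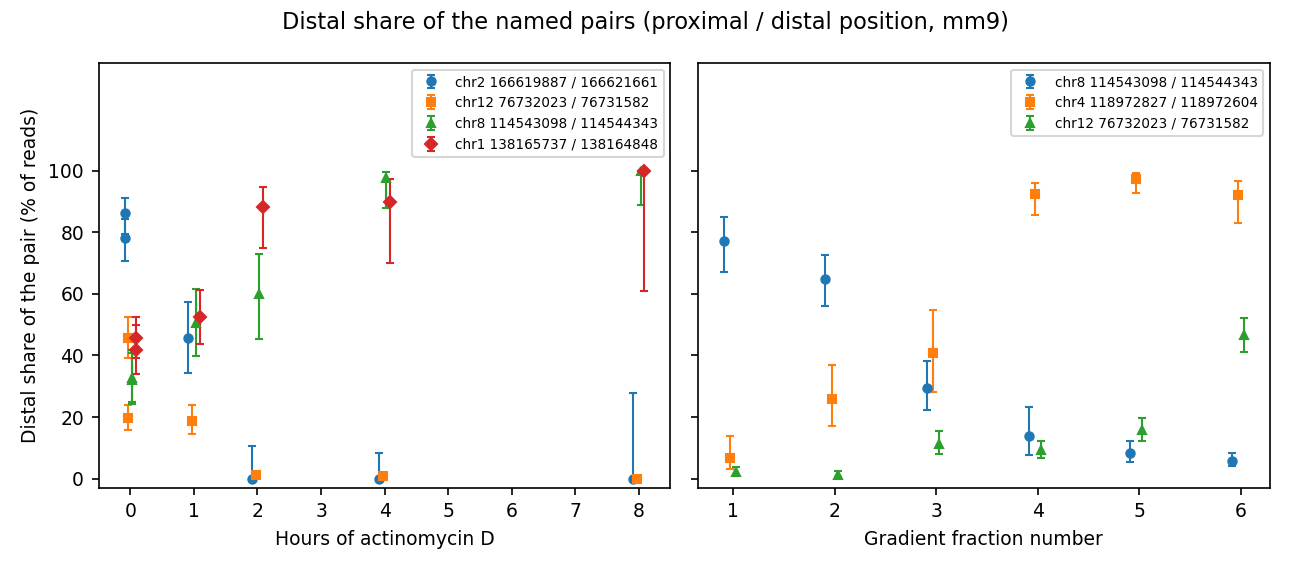
Share of the pair's reads at the distal 3' end (%, points, 1 per library) with Wilson 95% intervals (bars), against hours of actinomycin D for 4 named pairs (left, both controls at 0 h) and against gradient fraction number for 3 named pairs (right). The pair on chromosome 2 fell from 78.3% and 86.2% to 0 reads, and the pair on chromosome 4 rose from 6.74% in fraction 1 to 92.2% in fraction 6.

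Over the typical pair, the distal end lost ground with time. The median log2 distal/proximal ratio was 0.34 and 0.38 in the controls, 0.34 at 1 h, 0.25 at 2 h, 0.22 at 4 h and 0.16 at 8 h. It fell with hours with a Pearson r of -0.93 (exact permutation p = 0.00556, adjusted over 4 correlations 0.0222) and a Spearman rho of -0.90 (exact permutation p = 0.0278, adjusted 0.0444, two-sided, 6 libraries). Without the 4 and 8 h libraries r was -0.89. The labels name no sequencing batch, and the library total also fell with hours. In the authors' deposited table, the distal end had the shorter half-life in 57.1% of 3609 pairs with both ends past the filter, with medians of 3.33 h for proximal and 3 h for distal ends, and 16.1% of pairs differed at least 2-fold in half-life, not in the ratio over 8 h. These half-lives rest on the same 6 libraries, so they are no separate support. Between the controls alone, the ratio was lower in control 1 for 57.6% of 1779 pairs with at least 300 counts per end.

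**Figure D2:**
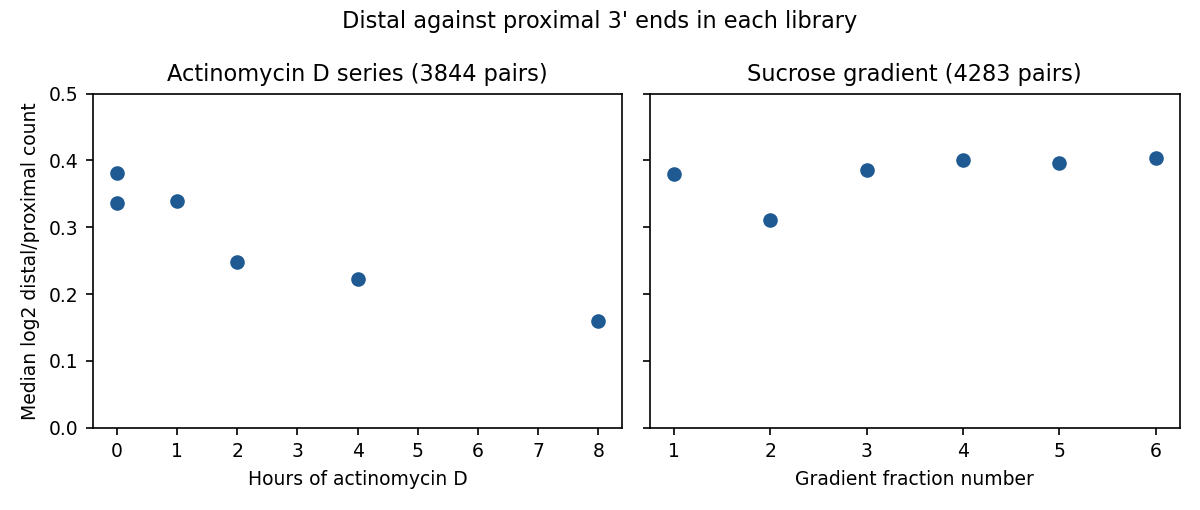
Median over pairs of the log2 ratio of distal to proximal counts in each library (points), against hours of actinomycin D (left, 3844 pairs) and against gradient fraction number (right, 4283 pairs). The medians fell from 0.34 and 0.38 in the controls to 0.16 at 8 h and lay between 0.31 and 0.40 over the fractions.

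Pairs farther apart were called more often. Of pairs under 100 nt apart, 26 of 1229 were called for stability (2.12%, Wilson 95% interval 1.45 to 3.08). Of pairs at least 1000 nt apart, 63 of 914 were (6.89%, interval 5.42 to 8.72). The median size of the slope difference rose from 0.053 to 0.11 log2 per hour between these groups, and its median SE from 0.057 to 0.076. The called shares rested on single libraries. On the same pairs, 24 far and 14 close pairs were called without control 1, where the Wilson intervals overlapped, 20 and 4 without the 1 h library, and 52 and 16 without the 2 h library. Without control 2 edgeR called 8 and 0 (243 and 173 at an unadjusted p under 0.05), without the 4 h library 10 and 0 (258 and 207) and without the 8 h library 0 and 0 (188 and 109). With all 6 libraries, 269 far and 209 close pairs were under that unadjusted p.

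**Figure D3:**
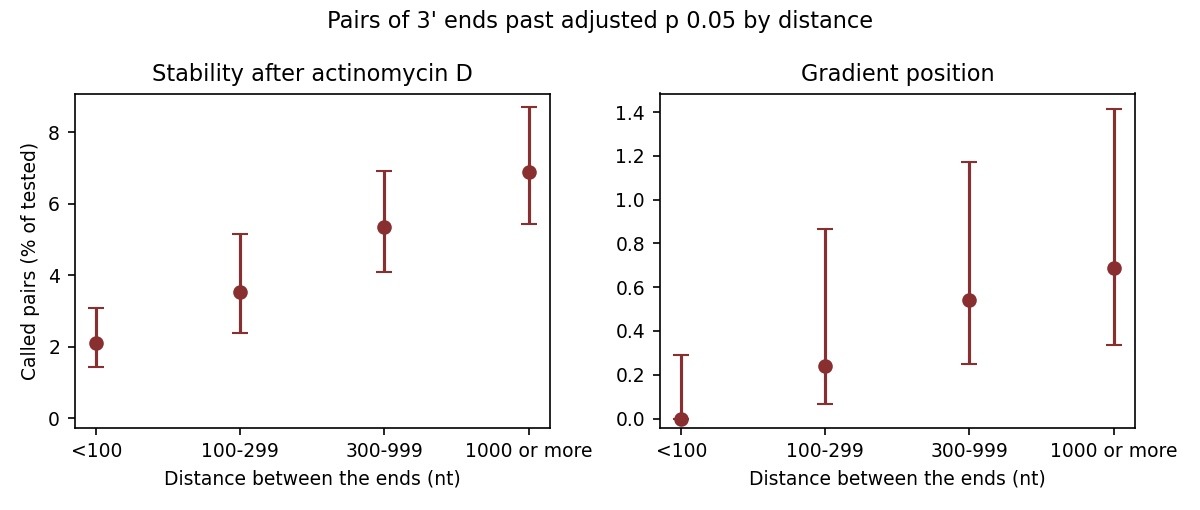
Percent of pairs called (points) with Wilson 95% intervals (bars) by the distance between the ends in nt, for stability after actinomycin D (left) and for gradient position (right, on its own scale). For stability the share rose from 2.12% below 100 nt to 6.89% at 1000 nt or more.

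The gradient asked how mRNAs distribute between light and heavy fractions. Of 11135 loci tested, 542 fell towards the heavy fractions, with a median slope of -0.88 log2 per fraction, and 59 rose, with a median of 0.62 (edgeR, adjusted p under 0.05). A 3' end on chromosome 5 (plus strand, 72641983) went from 188 CPM in fraction 1 to 8.63 in fraction 2 and 0.432 in fraction 6, 434-fold lower by library totals (5 counts in fraction 6, slope -2.11 ± 0.22, edgeR adjusted p = 2.62e-08). The ratio of CPM was 0.0023 (exact 95% interval 0.00074 to 0.0054). It depends on the scaling, and with the header's factors the slope was -1.51. An end on chromosome 3 (minus strand, 79454805) went from 101 to 26.8, 9.3, 1.52, 0.768 and 0.346 CPM over fractions 1 to 6 (slope -1.82 ± 0.19, edgeR adjusted p = 2.31e-08). Towards the heavy fractions, an end on chromosome 8 (plus strand, 32270557) rose from 1 count in fraction 1 to 163 in fraction 6, a ratio of CPM of 23.4 (exact 95% interval 4.15 to 931, slope 0.88 ± 0.21, edgeR adjusted p = 0.00606). Its adjusted p was 0.0515 without fraction 2 and 0.0556 without fraction 5. Another end on that chromosome (minus strand, 59010320) had 0 counts in fraction 1 and 193 in fraction 6 (slope 0.87 ± 0.20, edgeR adjusted p = 0.00526). By library totals, its ratio of CPM had an exact 95% lower limit of 7.45.

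These gradient counts also moved with single libraries and with the scaling. Falling and rising loci numbered 907 and 472 without fraction 1, 221 and 13 without fraction 2, 458 and 22 without fraction 3, 184 and 10 without fraction 5, and 258 and 87 without fraction 6. The authors' factors moved the median slope from 0.046 to 0.50 log2 per fraction and called 121 falling and 4476 rising, 97.4% rising against 9.8% with TMM.

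Few pairs of 3' ends were called over the gradient. Of 4283 pairs, 13 had a distal end that lay in heavier fractions than the proximal end and 2 had a distal end in lighter ones (edgeR, adjusted p under 0.05), while DESeq2 called 42 and 10. The median difference of slopes was 0.013 log2 per fraction, with the middle 50% between -0.065 and 0.10. For 848 pairs (19.8%), the 95% interval lay wholly within a 2-fold change from fraction 1 to 6, and for 45 it lay wholly beyond one. These intervals are not adjusted over the pairs tested either, so 45 is not a count of called differences. The median interval reached 0.21 log2 per fraction to either side, so for most pairs a 2-fold difference was not detectable. On chromosome 4 (minus strand, proximal 118972827, distal 118972604), the distal share rose from 6.74% in fraction 1 to 40.8% in fraction 3 and 92.2% in fraction 6 (slope difference 1.95 ± 0.23, edgeR adjusted p = 0.0223). The pair on chromosome 12 named above (76732023 and 76731582) went from 2.07% to 46.7% (1.13 ± 0.16, edgeR adjusted p = 0.0312), and the pair on chromosome 8 (114543098 and 114544343) from 77.1% to 5.83% (-1.22 ± 0.10, edgeR adjusted p = 0.00422). The adjusted p was 0.165, 0.177 and 0.0595 without fraction 2, and 0.159, 0.146 and 0.0592 without fraction 5, for the pairs on chromosomes 4, 12 and 8. It was 0.0528 without fraction 1 and 0.0582 without fraction 3 for the pair on chromosome 4, and 0.0576, 0.0844 and 0.121 without fractions 3, 4 and 6 for that on chromosome 12. Without fraction 1, 21 pairs with a heavier and 6 with a lighter distal end were called, without fraction 3 0 and 1, without fraction 4 3 and 1, and without fraction 6 11 and 3. Without fraction 2 or fraction 5, edgeR called 0 in each direction, with 289 and 205 (fraction 2) and 275 and 130 (fraction 5) at an unadjusted p under 0.05. With all 6 fractions, 375 and 181 pairs were under that unadjusted p.

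Over the typical pair, the median log2 distal/proximal ratio was 0.38, 0.31, 0.39, 0.40, 0.40 and 0.40 in fractions 1 to 6. Its Pearson r with fraction number was 0.60 (exact permutation p = 0.217, adjusted 0.217) and its Spearman rho 0.89 (exact permutation p = 0.0333, adjusted 0.0444), so only the ranked relation was past the threshold. The exact permutation p of rho was 0.0833 without fraction 2, 3, 4 or 5, 0.233 without fraction 6, 0.103 with the most proximal and most distal ends and 0.242 with at least 300 counts per end, so the ranked relation rests on these choices. Without fractions 1 and 6 r was 0.83. Of pairs under 100 nt apart, 0 of 1318 were called by edgeR, with 67 at an unadjusted p under 0.05, which allows a share of up to 0.291% (Wilson). Of pairs at least 1000 nt apart, 7 of 1017 were called (0.688%, Wilson interval 0.334 to 1.41), but 16 without fraction 1, 10 without fraction 6, 1 without fraction 3 or 4, and 0 without fraction 2 or 5 (183 and 178 at an unadjusted p under 0.05). In the authors' deposited table, 0.262% of 3812 pairs differed at least 2-fold in ribosomes per mRNA, with medians of 6.47 ribosomes for proximal and 6.48 for distal ends.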

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

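The linkage distances, single 3' ends, header factors, authors' filter, minimum distance, thinning and fraction-name covariate were chosen after seeing the data. The gene list settings and the settings for stem cells against 3T3 cells were not run. The cause of the moves below was not tested, except that leaving out a library removes samples and a count minimum changes how many features are tested. No paired analysis was possible because the groups share no replicate numbers that pair them.

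Counts of loci after actinomycin D moved by over 1.5 times only with the header's factors (259 rising, 6441 falling). Without each library they ranged from 2051 to 2586 rising and from 2676 to 3315 falling. Pairs with a slower and a faster distal end numbered 71 and 262 with DESeq2, 87 and 220 with ends linked within 5000 nt, and 74 and 195 with ends at least 100 nt apart. Without each library they ranged from 0 to 31 and from 0 to 101. Pearson's r of the median distal/proximal ratio with hours stayed past the threshold in every setting run, from -0.97 to -0.92 without each library, while the exact permutation p of Spearman's rho was 0.0833 without control 2 and 0.133 without the 4 h library.

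Loci rising and falling over the gradient numbered 148 and 887 with DESeq2, 33 and 353 with a minimum of 300 counts, 189 and 893 with no filter, 4476 and 121 with the header's factors, and 122 rising with the fraction-name covariate. Without each library they ranged from 10 to 472 and from 184 to 907. Pairs with a heavier and a lighter distal end numbered 42 and 10 with DESeq2, 31 and 5 with the most proximal and most distal ends, 5 and 0 with a minimum of 300 counts per end, 23 and 10 with a minimum of 10, 8 and 1 with ends linked within 1000 nt, 23 and 11 within 5000 nt, 54 and 17 at least 100 nt apart, 27 and 7 with thinned libraries, and 0 and 0 with the fraction-name covariate (edgeR, 313 and 152 at an unadjusted p under 0.05). The 0 at the minimum of 300 counts stands beside 114 at an unadjusted p under 0.05. Without each library they ranged from 0 to 21 and from 0 to 6. Pearson's r of the median ratio with fraction number passed the threshold with an added count of 5 (r = 0.91), and ranged from 0.49 to 0.98 without each library, past the threshold without fraction 1 (0.82) and without fraction 2 (0.98). Spearman's rho stayed past it only with an added count of 5 and without fraction 1.

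For named loci and pairs, the rule required the same direction in every fit without 1 library, where 64 fits kept the call and 26 lost it. Under the other settings run, 58 fits kept the direction and the call and 4 kept the direction and lost the call. Depth was lowest in fraction 1, with 1663346 counts.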

Other observations

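The groupings of loci by number of 3' ends and by abundance, the overlap of the stability and gradient calls, the test of the excess of pairs over other orders of the libraries and the shares by distance without each library were chosen after the results were seen. The other tests of explanations were fixed before their results were seen.

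Of 5 equal groups of loci by control abundance, the most abundant had the highest median slope after actinomycin D, without a steady trend below it. In this group (median 187 CPM), 49% rose and 21.6% fell, with a median slope of 0.078 log2 per hour. From the lowest group (4.43 CPM) to the fourth lowest (64.4 CPM), 15.1%, 12.4%, 16.8% and 25.1% rose and 19.1%, 37.5%, 41.5% and 38.8% fell, with median slopes of -0.023, -0.11, -0.092 and -0.044. The lowest group was called falling less often than the top, though its median slope was lower. Shares called also depend on counts, which were fewest in the lowest group. The controls that set the groups are also the starting points of the slopes. Noise in the controls therefore moves group and slope in opposite directions. Loci low in the controls could also reach the minimum count through high counts after treatment. Both effects would raise the slope of the lowest group, so its place among the groups cannot be read as stability. The shares depend on the scaling: with the header's factors 5.64% of the top group rose and 50.2% fell (median slope -0.085), and of the lowest 2% and 41% (-0.19). The median slope of the top group lay above that of the lowest in every fit that left out 1 library. The difference was 0.10 with all libraries and ranged from 0.046 (without control 2) to 0.15 (without the 8 h library). Of loci with 4 or more 3' ends 37% fell and of loci with a single end 27.5%, with median slopes of -0.056 and -0.013, but their median control levels were 47.9 and 21.6 CPM. Within the 5 abundance groups the loci with 4 or more ends had the higher falling share in 5 of 5, with Wilson 95% intervals apart in 2, and differences in median slope between -0.10 and -0.015 log2 per hour. In the authors' deposited table, ribosomes per mRNA had medians of 6.16 at sites of single-end loci and 6.45 at sites of loci with several ends.

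More pairs lost the distal end than gained it after actinomycin D. Of 100 orders of the 6 libraries, 1 gave as many called pairs in both directions together, the real one with 167, the highest of the others giving 131. That count says nothing of the excess. As large an excess of falling over rising pairs came from 2 of the 100, the real order with 87 and one that exchanged a control with the 1 h library with 91. This test cannot judge the direction, since nearly all other orders called 0 pairs and so had no excess to compare. The excess remained when library totals were made equal: with each library thinned to the smallest total, 77.1% of 223 called pairs had the distal end falling (Wilson 95% interval 71.2 to 82.2). Thinning did not equalise the depth of the pairs. By the TMM factors, 0.66 at 8 h and 1.22 and 1.29 in the controls, a typical locus held a smaller share of the reads at 8 h. Lower depth of the pairs at 8 h is therefore not excluded. As a test of loci that join neighbouring genes, the excess also remained among called pairs under 500 nt apart, where 54 of 70 fell (77.1%, interval 66 to 85.4). Both intervals take pairs as independent, but all pairs share the same 6 libraries, so a shift of whole libraries is not excluded. A shorter life of the longer isoform remains a hypothesis: without the 8 h library edgeR called 0 pairs (412 falling and 166 rising at an unadjusted p under 0.05), while the slope of the median distal/proximal ratio was -0.036 log2 per hour against -0.026 with it. The loss of the distal end was also not confined to ends far apart. Its median slope difference was -0.018 log2 per hour under 100 nt and -0.018 from 100 to 300 nt. It was -0.019 from 300 to 1000 nt and -0.025 at 1000 nt or more. Of the 26 called pairs under 100 nt apart, 23 fell.

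Ends far apart were called for stability more often than ends close together, and read depth of the pairs alone did not give this: among the pairs with the most counts, 12.3% of those at least 1000 nt apart were called (Wilson interval 8.82 to 16.8) and 3.49% of those under 100 nt (2.19 to 5.52). Over all pairs the shares were 6.89% and 2.12%, and the far pairs had the higher share in each of 3 groups by counts. The calls rest on single libraries: edgeR called 8 far and 0 close pairs without control 2 (243 and 173 at an unadjusted p under 0.05), 10 and 0 without the 4 h library (258 and 207) and 0 and 0 without the 8 h library (188 and 109), and without control 1 the Wilson intervals of the shares overlapped, but the median size of the slope difference of far pairs was between 1.94 and 2.19 times that of close pairs without each library. This is consistent with the hypothesis that the sequence between the 2 ends carries differences in stability, but far pairs may also belong to different genes more often, which was not tested without an annotation of mm9.

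Stable mRNAs did not lie in heavier fractions. Across loci, which are not independent replicates, Spearman's rho between the slope on hours and the slope on fraction number was -0.12 over 10458 loci, and between -0.19 and -0.11 in 5 groups by abundance, where the hypothesis required above 0.1. Across 3312 pairs tested in both, rho was -0.032 (bootstrap 95% interval -0.069 to 0.0034), where the hypothesis again required above 0.1. For most pairs a 2-fold difference was not detectable in either slope, and noise draws rho towards 0. This rho therefore leaves open where the more stable end of a pair lay. Of the 3312 pairs, 139 were called for stability and 13 for gradient position, and 4 for both, against 0.546 for independent lists, or 0.825 within groups of like counts and distance. In 4 of these 4, among them the pairs on chromosomes 8 and 12 named in the report, the more stable end lay in the lighter fractions. The 4 rest on single libraries, since edgeR called 0 pairs for gradient position without fraction 2 (289 rising and 205 falling at an unadjusted p under 0.05) or fraction 5 (275 and 130), and 0 for stability without the 8 h library (412 falling and 166 rising), which leaves no overlap.

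The counts of loci were set against other orders of the libraries as well. For actinomycin D, 1 of 100 orders gave as many as the real 5945, the highest of the others giving 4984. For gradient loci, 3 of 100 gave as many as the real 601, the highest of the others giving 1086, and for gradient pairs 1 of 100 gave as many as the real 15, the highest of the others giving 0. Each share was under 0.05, which goes against an arbitrary order of the libraries but not against another trend along them. Library totals also rose with fraction number, from 1663346 to 11575417 counts. For gradient loci an order that exchanged fractions 1 and 3 gave the 1086, and one that exchanged 1 with 2 and 5 with 6 gave 750. Both lie above the real count, so the real order was not singled out.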
